A study of Mus musculus with 16 samples.

How the data were processed

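Livers of 16 male mice, 4 months old, were measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array per liver. All mice carried a transgene that expresses methylmalonyl-CoA mutase, the enzyme encoded by Mut (now named Mmut), in muscle. Besides the transgene the mice were either heterozygous or homozygous mutant at the Mut locus, and each genotype was sampled unfasted and fasted, which gave 4 groups of 4 arrays. The heterozygotes had fasted for 12 hours and the mutants for 8 to 12 hours, so the fast was not matched between genotypes. The series' design text describes separate mice in each group. No batch or scan date was used, since the labels give none.

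The authors deposited 1 table of processed values. Per the submitters' processing notes it was made with Affymetrix Expression Console and RMA, a method that corrects background, normalizes arrays by quantiles and summarizes the probes of each probe set. The versions, the library file, the genome build and any filter were not given in the sources used here. Per the labels' protocols, 300 ng of total RNA was labelled for each array. The deposited values were taken to be on the log2 scale from their range of 3.80 to 14.33, and array medians lay between 7.33 and 7.40. The table holds 35556 probe sets and has no detection calls, so no probe set was called absent, and a change of a dim probe set can be understated. For arrays only their number limits the precision stated here. No 2 arrays held identical values, and correlations between arrays of 1 group ranged from 0.986 to 0.998.

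Probe sets were named from the platform's annotation, with symbols updated by gene number through a RefSeq gene table of the assembly GRCm38.p6. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed. Of those with 1 symbol, 21698 matched the gene table and 91 kept the annotation's symbol. Probe sets with several symbols or none were left out of the comparisons. Where a gene had several probe sets (999 genes), the one with the highest mean over all arrays was used, which left 19938 genes. No filter on dim genes was applied. No coordinates are given, because the build behind the annotation was not named.

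Differences were tested with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 16 arrays, so that the groups shared 1 estimate of each gene's spread. The variance was moderated with a trend on intensity (eBayes), tests were two-sided, and p-values were adjusted over all genes by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 are called. The 5 contrasts were mutant against heterozygous in each feeding state, fasted against unfasted in each genotype, and the interaction of genotype and fasting. Values are given as log2 differences ± standard error from this fit, with 4 arrays per group, unless stated otherwise. Tests were checked on simulated data for 19938 genes, with independent noise and 1 fitted spread per gene shared by all groups. Of genes changed by 0.5 log2 units, 91% were called in the unfasted genotype contrast and 82.1% in the fasted one. The share was 89.6% in each fasting contrast and 64.2% in the interaction. The 4 pairwise contrasts had equal power by this design, so differences between their shares reflect the draw of genes and noise.

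There were 38 gene lists of pathways and cell type markers, tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and adjusted over the lists within a contrast. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance. Members past the threshold were counted after adjustment over all genes and after adjustment over the list alone. Genes were named by a rule: in each pairwise contrast the 10 largest rises and the 10 largest falls among called genes whose 4 arrays of one group all lay on one side of the other group's 4, all called interaction genes up to 6 in each direction, Mmut, Fgf21, Igf1, Cpt1a and Ppargc1a in every contrast, and up to 4 called members with the largest change in each list described. Predicted genes, clones and olfactory or small RNA genes were counted but not named. Genes outside the rule are stated to have been chosen after their values were seen. A further gene that the rule names was not analysed here.

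The groups, contrasts, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where a choice is said to have been made after seeing the data. The alternatives were a replicate block, a fit of only the arrays compared, array weights, median-centred arrays, a second quantile normalization, variance moderation without a trend or with robust settings, the mean over probe sets, only genes above the median brightness, a 2-fold minimum, a stricter threshold of 0.01, and leaving out each array in turn. Counts were also set against those from all 35 splits of the 8 arrays of each pairwise contrast and from 100 drawn splits for the interaction. For the interaction the same splits were also run on exchanged residuals, a test chosen after seeing the data.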

Results

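Liver RNA from mutant and heterozygous mice, all with the muscle transgene, was profiled in the unfasted state and after a fast, with 4 arrays in each of the 4 groups. The study concerns methylmalonic acidemia, in which loss of methylmalonyl-CoA mutase blocks the breakdown of propionate-forming amino acids and odd-chain fatty acids, and the series' title refers to hormesis, an adaptive response to a mild stress. Mmut itself, the targeted gene, read 9.82 ± 0.11 (SD, n = 4) in unfasted and 9.89 ± 0.15 in fasted heterozygotes, against 8.04 ± 0.20 in unfasted and 8.09 ± 0.20 in fasted mutants, on the log2 scale. All 8 mutant arrays lay below all 8 heterozygous ones, so the labels and the targeted gene matched. The difference was -1.78 ± 0.11 in the unfasted state (limma, adjusted p = 7.5e-07) and -1.80 ± 0.11 in the fasted state (adjusted p = 3.6e-07). The first principal component held 40.6% of the variance and separated the genotypes, and the next held 13.5% and separated the feeding states. The median SD of a gene within a group was 0.11 log2 units in unfasted mutants, 0.09 in fasted mutants, 0.07 in unfasted and 0.07 in fasted heterozygotes. One unfasted mutant array, replicate 1, carried transcripts of pancreatic acinar cells, which make digestive enzymes. Cpa1 (carboxypeptidase A1) read 12.29 there and between 6.84 and 7.22 on the 15 other arrays, and Ctrb1 (chymotrypsinogen) 12.64 against 7.16 to 7.63.

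**Figure D1:**
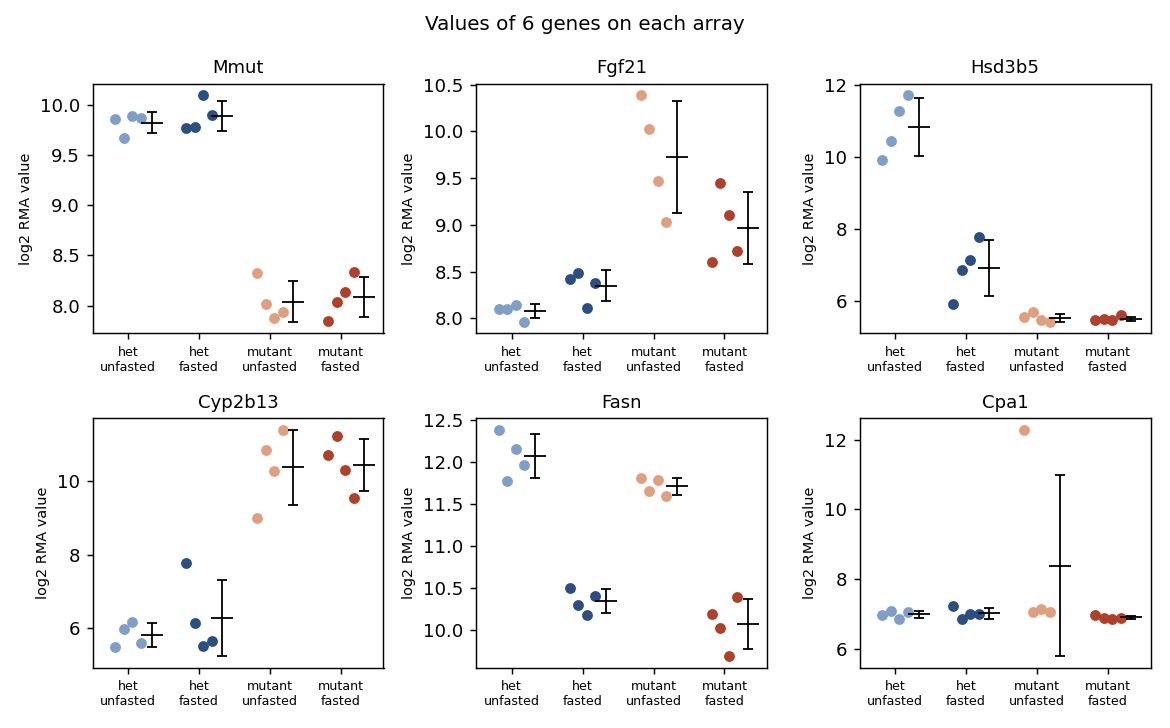
Log2 RMA values (vertical axes) of 6 genes in each group (horizontal axes), with 1 point per array and a bar for the mean ± SD over 4 arrays. Mmut lay lower on every mutant array, Fgf21 was highest in unfasted mutants, Hsd3b5 was high in unfasted heterozygotes, Cyp2b13 was high in mutants, Fasn was low after fasting, and Cpa1 stood at 12.29 on 1 unfasted mutant array.

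The first comparison asked how the unfasted mutant liver differed from the heterozygous one. Cytochromes P450 that are known to be higher in female than in male mouse liver rose, led by Cyp2b13 at 4.57 ± 0.51 (23.7-fold, adjusted p = 0.00013), Cyp2b9 at 3.99 ± 1.001 and Cyp2a22 at 3.68 ± 0.45. Genes known to be higher in males fell, led by Hsd3b5, a steroid dehydrogenase, at -5.29 ± 0.35 (39-fold, adjusted p = 7.5e-07) and Elovl3, a fatty acid elongase, at -4.17 ± 0.70. Hsd3b5 was dim in mutants, so the size of its fall can be understated. Fgf21, a liver hormone released in metabolic stress, rose by 1.65 ± 0.23 (adjusted p = 0.00072), as did Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, by 2.83 ± 0.46 and Asns, asparagine synthetase, by 2.65 ± 0.53. Slc7a11, the cystine transporter, rose by 3.50 ± 0.82, Pdk4, a kinase that restrains pyruvate oxidation, by 2.17 ± 0.39, and the transporters Slc22a26 by 2.54 ± 0.31, Abcd2 by 2.14 ± 0.39 and Abcc4 by 2.13 ± 0.24. Further large falls were those of Serpina4-ps1 at -5.09 ± 0.67, Obp2a at -3.78 ± 0.34, Orm1 (an acute phase protein) at -3.04 ± 0.63, Slco1a1 at -2.98 ± 0.86, Cyp7b1 at -2.76 ± 0.24, Mup21 at -2.65 ± 0.39, Slc10a2 at -2.36 ± 0.33 and C9, a complement component, at -2.27 ± 0.46. In all, 1584 of 19938 genes were called, 848 higher and 736 lower. Without heterozygous replicate 3 of the unfasted group the count was 698 and without its replicate 4 it was 815, while without mutant unfasted replicate 3 it was 1033. In a fit of only these 8 arrays it was 764. Slco1a1 lost its call without any 1 of 12 arrays, Cyp2b9 without any 1 of 3 and Slc7a11 without 1, with adjusted p up to 0.13, 0.078 and 0.052.

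Stress-response and growth groups moved in different directions in unfasted mutants. Of 29 measured genes of the integrated stress response driven by the transcription factor ATF4, 15 rose, none fell and 14 did not pass (21 rose when adjusted over the list alone, camera adjusted p = 4.4e-14). Vldlr rose by 1.64 ± 0.25 beside Slc7a11, Asns and Fgf21. The list had an adjusted p = 0.084 with an estimated correlation. Of 21 genes of the endoplasmic reticulum stress list, mostly chaperones and folding enzymes, 13 fell and 8 did not pass (18 fell when adjusted over the list alone, camera adjusted p = 2.0e-15, and adjusted p = 0.084 with an estimated correlation). Sdf2l1 fell by 1.32 ± 0.18, Ero1b by 1.02 ± 0.19, Derl3 by 0.80 ± 0.14 and Creld2 by 0.77 ± 0.19. Cell cycle genes were higher, with 13 of 23 past the test and none lower (18 when adjusted over the list alone, camera adjusted p = 2.5e-12, and adjusted p = 0.084 with an estimated correlation). Ccnd1, cyclin D1, rose by 1.82 ± 0.28, the replication helicase gene Mcm6 by 0.89 ± 0.17, Mki67 by 0.82 ± 0.17 and Top2a by 0.69 ± 0.13. Unfasted mutant replicate 1 held the acinar transcripts, with Cpa1 at 12.29. Without that array, an alternative added after seeing the data, 12 ATF4 genes rose, 17 endoplasmic reticulum stress genes fell and 17 cell cycle genes rose. Creld2 lost its call without any 1 of 4 arrays (adjusted p up to 0.083).

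Sex-biased and metabolic genes followed. In the list of the growth hormone axis and male-biased genes 13 of 19 fell and none rose (14 fell when adjusted over the list alone, camera adjusted p = 3.7e-15, and adjusted p = 0.084 with an estimated correlation). In the female-biased list 8 of 14 rose and none fell (8 when adjusted over the list alone, camera adjusted p = 6.9e-09), and this call held with an estimated correlation (adjusted p = 0.010). Igf1, insulin-like growth factor 1, was lower by a small amount, -0.21 ± 0.06 (adjusted p = 0.040), and lost its call without any 1 of 8 arrays, with adjusted p up to 0.13. Of 29 targets of PPAR-alpha, the nuclear receptor of the fasted liver, 9 rose and none fell (17 rose and 2 fell when adjusted over the list alone, camera adjusted p = 1.6e-08, and adjusted p = 0.26 with an estimated correlation). Acot2 rose by 1.93 ± 0.30 and Acot1 by 1.17 ± 0.33. Of 17 genes of mitochondrial beta-oxidation and ketogenesis, 4 rose and none fell (5 when adjusted over the list alone, camera adjusted p = 5.5e-05, and adjusted p = 0.31 with an estimated correlation). Hadhb rose by 0.46 ± 0.09 and Acadl by 0.44 ± 0.08. Srebf1, the master regulator of lipogenesis, fell by 1.10 ± 0.17, as did 3 other of the 24 fatty acid and triglyceride genes, with none higher (4 fell when adjusted over the list alone, camera adjusted p = 0.049, and adjusted p = 0.52 with an estimated correlation). This last camera call was lost without any 1 of 6 arrays, with adjusted p up to 0.43. Of 20 cholesterol synthesis genes 4 rose, led by Lss at 0.98 ± 0.22, and none fell (11 when adjusted over the list alone, camera adjusted p = 3.3e-05, and adjusted p = 0.38 with an estimated correlation). Without unfasted mutant replicate 1, which held the acinar transcripts, 7 PPAR-alpha targets rose and 1 fell, 2 beta-oxidation genes rose, 9 male-biased genes fell and 8 female-biased genes rose. Acot1 lost its call without any 1 of 8 arrays, with adjusted p up to 0.14.

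Genes of other liver cell types were higher as well. Of 15 endothelial markers 10 rose and none fell (12 when adjusted over the list alone, camera adjusted p = 3.1e-11, and adjusted p = 0.084 with an estimated correlation). Lyve1 rose by 1.37 ± 0.31 and Aqp1 by 0.58 ± 0.11. Of 17 stellate cell and fibroblast markers 8 rose and none fell (11 when adjusted over the list alone, camera adjusted p = 1.5e-07, and adjusted p = 0.12 with an estimated correlation). Pdgfra rose by 0.51 ± 0.08 and Pdgfrb by 0.49 ± 0.10. None of 19 macrophage markers passed singly (4 were higher when adjusted over the list alone), although the list lay above other genes with a median of 0.27 (camera adjusted p = 5.6e-05, and adjusted p = 0.36 with an estimated correlation). Gpnmb read 0.60 ± 0.20 higher (adjusted p = 0.073). Of 12 neutrophil markers 2 rose (7 when adjusted over the list alone, camera adjusted p = 0.0019, and adjusted p = 0.18 with an estimated correlation). None of 9 cholangiocyte markers passed (3 were higher when adjusted over the list alone, camera adjusted p = 0.041, and adjusted p = 0.46 with an estimated correlation), a camera call lost without any 1 of 4 arrays (adjusted p up to 0.19). None of 17 lymphocyte markers passed, and that list was not called (none when adjusted over the list alone, camera adjusted p = 0.31). Of 13 periportal hepatocyte genes 5 fell and none rose (5 when adjusted over the list alone, camera adjusted p = 0.011, and adjusted p = 0.18 with an estimated correlation). Hal, histidine ammonia-lyase, fell by 1.35 ± 0.26 and Cyp2f2 by 0.75 ± 0.17. Of 64 oxidative phosphorylation subunits 1 was lower, Ndufb3 at -0.31 ± 0.07, and the list was not called (1 when adjusted over the list alone, camera adjusted p = 0.90), though it was without unfasted mutant replicate 3 (adjusted p = 0.046). Of 22 genes of branched-chain amino acid and propionate catabolism, the pathway that holds Mmut, 4 fell and none rose (5 when adjusted over the list alone, camera adjusted p = 0.0029, and adjusted p = 0.46 with an estimated correlation). Acadsb fell by 0.70 ± 0.15, and the camera call was lost without unfasted mutant replicate 3 (adjusted p = 0.052). Mmut, which is lower by the genotype itself, was not taken out for this count or test. None of 13 pancreas and adipose markers passed, and their median was 0.70 higher (camera adjusted p = 0.087) with unfasted mutant replicate 1 and 0.02 higher without it. Leaving out any 1 of the other 3 unfasted mutant arrays gave that list a call, with adjusted p down to 0.014. Lyve1 lost its call without any 1 of 2 arrays (adjusted p up to 0.055). Camera also called bile acid (adjusted p = 0.00029) and urea cycle genes (0.0060) as lower, and the tricarboxylic acid cycle (0.018) and the mitochondrial unfolded protein response (0.020) as higher. With an estimated correlation their adjusted p lay between 0.229 and 0.524. The tricarboxylic acid cycle lost its call without unfasted mutant replicate 1 or unfasted heterozygous replicate 4 (adjusted p up to 0.28), and the mitochondrial unfolded protein response without unfasted mutant replicate 1 (0.42).

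The second comparison set mutants against heterozygotes after the fast. The fast lasted 8 to 12 hours in mutants and 12 hours in heterozygotes, so genotype and fast length cannot be told apart here. The female-biased Cyp2b13 was again higher, at 4.16 ± 0.51 (17.9-fold, adjusted p = 0.00019), as were Cyp2b9 at 3.56 ± 1.001, Cyp2a22 at 3.11 ± 0.45, Slc7a11 at 3.50 ± 0.82 and Asns at 2.98 ± 0.53. Lepr, the leptin receptor, rose by 3.82 ± 0.59 (14.1-fold, adjusted p = 0.0010), Aqp7, a glycerol channel, by 2.66 ± 0.32, Prss8 by 2.39 ± 0.19, Abcc4 by 2.24 ± 0.24 and Cd63 by 2.22 ± 0.27. The largest fall by this rule was that of Elovl3 at -3.75 ± 0.70, followed by Orm1 at -3.65 ± 0.63, Nnmt (nicotinamide N-methyltransferase) at -3.45 ± 0.48, Slco1a1 at -3.30 ± 0.86, Obp2a at -3.19 ± 0.34, Slc3a1 at -3.11 ± 0.29, C9 at -2.89 ± 0.46, Serpina4-ps1 at -2.84 ± 0.67, Pigr at -2.74 ± 0.40 and Orm3 at -2.73 ± 0.34. Fgf21 was 0.61 ± 0.23 higher and did not pass (adjusted p = 0.086). Ppargc1a, a coactivator of mitochondrial and gluconeogenic genes, rose by 0.98 ± 0.27 (adjusted p = 0.023). The test called 2716 genes, 1718 higher and 998 lower. Leaving out mutant fasted replicate 2 gave 1575 and heterozygous fasted replicate 4 gave 1713. Cyp2b9 lost its call without any 1 of 5 arrays, Ppargc1a of 4 and Slco1a1 of 3, with adjusted p up to 0.087, 0.073 and 0.068. Of the 1584 genes called in the unfasted state, 831 were called here too, 829 with the same sign (531 higher and 298 lower), where independent lists would share 73.1 and 36.8. These 2 comparisons share no array.

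Macrophage and endothelial markers were higher in fasted mutants. Of 19 macrophage markers 13 rose and none fell (18 when adjusted over the list alone, camera adjusted p = 8.8e-10, and adjusted p = 0.32 with an estimated correlation). Gpnmb rose by 1.11 ± 0.20, Vsig4 by 0.91 ± 0.20, the complement gene C1qc by 0.84 ± 0.19 and Clec4f, a Kupffer cell lectin, by 0.82 ± 0.16. Of 15 endothelial markers 11 rose (14 when adjusted over the list alone, camera adjusted p = 6.2e-09, and adjusted p = 0.32 with an estimated correlation). Kdr rose by 0.58 ± 0.09 and Emcn by 0.58 ± 0.11. Of 17 lymphocyte markers 3 rose and 1 fell (4 and 1 when adjusted over the list alone, camera adjusted p = 0.0065, and adjusted p = 0.45 with an estimated correlation). Of 17 stellate cell and fibroblast markers 2 rose (3 when adjusted over the list alone, camera adjusted p = 0.037, and adjusted p = 0.52 with an estimated correlation), a camera call lost without fasted mutant replicate 1 or fasted heterozygous replicate 1 (adjusted p up to 0.35). Neutrophil and cholangiocyte markers were not called (camera adjusted p = 0.98 for both). In the ATF4 list 12 of 29 rose and 2 fell (16 and 2 when adjusted over the list alone, camera adjusted p = 1.6e-06, and adjusted p = 0.32 with an estimated correlation). Psat1, a serine synthesis enzyme, rose by 1.98 ± 0.38 and Nupr1 by 1.87 ± 0.40. In the endoplasmic reticulum stress list 3 of 21 fell and none rose (7 when adjusted over the list alone, camera adjusted p = 0.00081, and adjusted p = 0.45 with an estimated correlation). Of 15 genes of the mitochondrial unfolded protein response 6 rose (7 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.00074, and adjusted p = 0.45 with an estimated correlation), with the chaperone gene Hspa9 at 0.51 ± 0.09, and of 17 tricarboxylic acid cycle genes 6 rose (6 when adjusted over the list alone, camera adjusted p = 0.00015, and adjusted p = 0.32 with an estimated correlation). Idh2 rose by 0.51 ± 0.10 and Mdh2 by 0.50 ± 0.09.

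**Figure D2:**
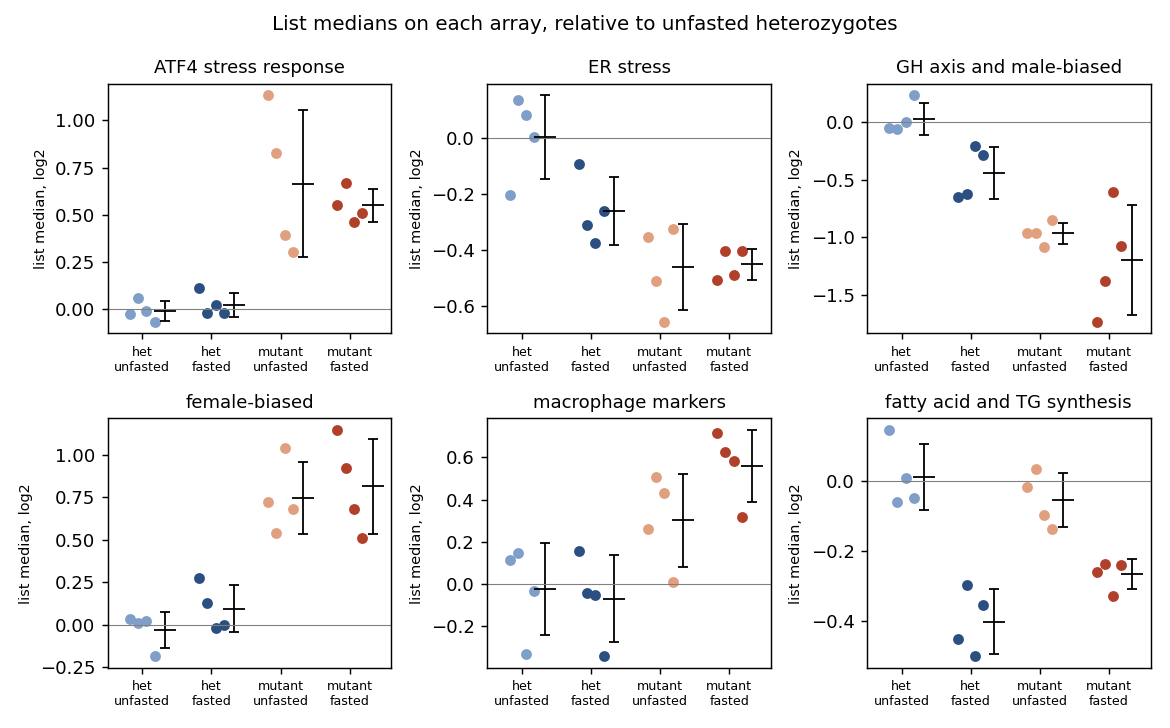
Median of 6 gene lists on each array (vertical axes, log2), relative to the mean of the unfasted heterozygotes for each gene, by group (horizontal axes), with 1 point per array and a bar for the mean ± SD over 4 arrays. ATF4 medians lay between 0.30 and 1.13 on the unfasted mutant arrays and between -0.06 and 0.06 on the unfasted heterozygous arrays, and the highest belongs to the array with acinar transcripts.

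Sterol, bile acid and acute phase genes also differed between the fasted groups, whose fasts were not matched. Of 20 cholesterol synthesis genes 11 were higher in mutants and 1 lower (13 and 1 when adjusted over the list alone, camera adjusted p = 5.2e-06, and adjusted p = 0.45 with an estimated correlation). Sqle, squalene epoxidase, rose by 1.58 ± 0.45, Cyp51 by 1.28 ± 0.29, Idi1 by 1.16 ± 0.29 and Lss by 1.14 ± 0.22. Of 17 bile acid genes 9 fell and none rose (10 fell and 1 rose when adjusted over the list alone, camera adjusted p = 2.9e-06, and adjusted p = 0.32 with an estimated correlation). Among those that fell were the oxysterol hydroxylase gene Cyp7b1 at -2.29 ± 0.24, Nr0b2 at -1.40 ± 0.31 and Akr1d1 at -1.02 ± 0.20. Of 22 acute phase genes 5 fell and 2 rose (8 and 2 when adjusted over the list alone, camera adjusted p = 0.0027, and adjusted p = 0.45 with an estimated correlation). The orosomucoid genes Orm1, Orm3 and Orm2 fell, the last at -2.56 ± 0.56, while Apcs rose by 1.20 ± 0.28. Otc, ornithine transcarbamylase of the urea cycle, fell by 1.21 ± 0.25, with 3 of the 9 urea cycle genes lower and none higher (4 when adjusted over the list alone, camera adjusted p = 0.018, and adjusted p = 0.35 with an estimated correlation). That camera call was lost without heterozygous fasted replicate 3 (adjusted p = 0.051). The male-biased list had 9 of 19 lower (13 lower and 2 higher when adjusted over the list alone, camera adjusted p = 1.2e-05, and adjusted p = 0.32 with an estimated correlation) and 1 higher, Socs2, a growth hormone-induced inhibitor of cytokine signalling, at 2.20 ± 0.44. The female-biased list had 7 of 14 higher and none lower (8 when adjusted over the list alone, camera adjusted p = 0.00011, and adjusted p = 0.16 with an estimated correlation). Sqle lost its call without any 1 of 6 arrays (adjusted p up to 0.089) and Idi1 without 1 (0.055). Camera also called cell cycle genes (adjusted p = 9.1e-05), PPAR-alpha targets (0.00011), beta-oxidation (0.0022) and mitochondrial biogenesis (0.033) as higher, and pericentral genes (0.0091) and branched-chain amino acid catabolism (0.018) as lower. With an estimated correlation their adjusted p lay between 0.32 and 0.541. Mitochondrial biogenesis lost its call without any 1 of 3 arrays (adjusted p up to 0.14) and branched-chain amino acid catabolism without any 1 of 2 (0.16). Mmut, lower by the genotype itself, was not taken out for the test of branched-chain amino acid catabolism.

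The third comparison gave the fasting response of heterozygotes. Lipogenic genes fell, among them Thrsp at -2.83 ± 0.36 (7.13-fold, adjusted p = 0.00097), Fasn, fatty acid synthase, at -1.72 ± 0.14, Srebf1 at -1.70 ± 0.17 and Elovl6 at -1.58 ± 0.14. Hsd3b5 fell by 3.91 ± 0.35 (15-fold, adjusted p = 3.9e-05). Further falls were those of Cyp2c55 at -1.92 ± 0.32, Hsd3b2 at -1.62 ± 0.36, Keg1 at -1.61 ± 0.28, Nsdhl, a cholesterol synthesis enzyme, at -1.497 ± 0.28 and Dpy19l3 at -1.495 ± 0.28. Cyp17a1, a steroid hydroxylase, rose by 2.17 ± 0.34 (adjusted p = 0.0064), Igfbp1 by 2.13 ± 0.46, Gadd45b by 1.91 ± 0.34, Orm3 by 1.54 ± 0.34, Rab30 by 1.501 ± 0.25, Fkbp5, a glucocorticoid-induced chaperone gene, by 1.46 ± 0.31, Slc16a5 by 1.29 ± 0.25, Cyp2c39 by 1.28 ± 0.20, Flvcr2 by 1.21 ± 0.19 and Acnat2 by 1.16 ± 0.24. The test called 313 genes, 146 higher and 167 lower. A fit of only these 8 arrays called 568, and array weights gave 1029, 510 higher and 519 lower. The count fell to 155 without heterozygous unfasted replicate 4, 163 without its replicate 3, and 163, 175, 168 and 180 without heterozygous fasted replicates 1, 2, 3 and 4. Igfbp1, Orm3 and Acnat2 each lost their call without any 1 of 5 arrays, Fkbp5 of 7, Hsd3b2 of 6 and Slc16a5 of 3, with adjusted p up to 0.11.

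By list, 11 of 24 fatty acid and triglyceride synthesis genes fell and none rose in fasted heterozygotes (15 when adjusted over the list alone, camera adjusted p = 1.1e-20), a call that held with an estimated correlation (adjusted p = 0.022). Of 20 cholesterol synthesis genes 9 fell and none rose (16 when adjusted over the list alone, camera adjusted p = 3.7e-21, and adjusted p = 0.11 with an estimated correlation). Fdps fell by 1.32 ± 0.22 beside Nsdhl. Of 29 PPAR-alpha targets 8 rose and none fell (16 when adjusted over the list alone, camera adjusted p = 2.7e-15, and adjusted p = 0.13 with an estimated correlation). Angptl4, a lipoprotein lipase inhibitor, rose by 1.08 ± 0.18 and Ehhadh by 0.79 ± 0.15. Of 17 beta-oxidation and ketogenesis genes 7 rose (11 when adjusted over the list alone, camera adjusted p = 2.7e-14, and adjusted p = 0.11 with an estimated correlation). Cpt1a, the gate of fatty acid entry into mitochondria, rose by 0.52 ± 0.10 (adjusted p = 0.015) and Acadm by 0.40 ± 0.07. Of 16 gluconeogenic and insulin-suppressed genes 3 rose (5 when adjusted over the list alone, camera adjusted p = 1.8e-06, and adjusted p = 0.11 with an estimated correlation). Pck1 rose by 0.60 ± 0.10. In the endoplasmic reticulum stress list 4 of 21 fell (10 when adjusted over the list alone, camera adjusted p = 7.8e-14, and adjusted p = 0.13 with an estimated correlation). Sdf2l1 fell by 0.95 ± 0.18. None of 23 cell cycle genes passed (none when adjusted over the list alone), although the list lay lower with a median of -0.165 (camera adjusted p = 3.4e-05, and adjusted p = 0.26 with an estimated correlation). Camera also called male-biased (adjusted p = 1.5e-10), interferon response (3.3e-09) and NRF2 antioxidant genes (0.038) as lower, and acute phase genes (0.00037) as higher. With an estimated correlation their adjusted p lay between 0.111 and 0.517, and the antioxidant call was lost without any 1 of 3 arrays (adjusted p up to 0.24). None of the 29 ATF4 genes passed in either direction (none when adjusted over the list alone, camera adjusted p = 0.84), and Fgf21 was 0.27 ± 0.23 higher (adjusted p = 0.74). Without heterozygous fasted replicate 3 Cpt1a (adjusted p = 0.054) and Sdf2l1 (adjusted p = 0.055) lost their calls.

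The fourth comparison gave the fasting response of mutants. The lipogenic genes Thrsp and Fasn fell here too, at -2.73 ± 0.36 (6.62-fold, adjusted p = 0.0026) and -1.64 ± 0.14, and Cyp17a1 rose by 1.82 ± 0.34. Ppargc1a rose by 1.33 ± 0.27 (2.52-fold, adjusted p = 0.015). On heterozygous arrays Ppargc1a read 8.48 to 8.66 unfasted and 8.89 to 9.7 fasted, and its interaction was not called. Got1, an aspartate aminotransferase, rose by 1.29 ± 0.29 in mutants, Fam13a by 1.25 ± 0.30, Nipal1 by 1.19 ± 0.12 and Gpcpd1 by 1.17 ± 0.30. Slc25a25 rose by 1.04 ± 0.21, Tbc1d8 by 1.01 ± 0.18, Slc41a3 by 0.98 ± 0.15 and Tmem120a by 0.92 ± 0.11. Other falls were those of Cyp2c55 at -2.03 ± 0.32, Hsd3b2 at -1.65 ± 0.36, Hsd3b3 at -1.61 ± 0.36, Angptl8, an insulin-induced secreted protein, at -1.48 ± 0.24, Osgin1 at -1.42 ± 0.26, Cyp2c70 at -1.25 ± 0.26, Ppp1r3b, a glycogen-targeting phosphatase subunit, at -1.24 ± 0.15 and Gstp3 at -1.17 ± 0.27. The test called 667 genes, 464 higher and 203 lower. Unfasted mutant replicate 1, the array with acinar transcripts, weighed on this count, which was 1941 without it (1050 higher and 891 lower), with 653 genes in common. It was 224 without mutant fasted replicate 2, 287 and 342 without mutant unfasted replicates 2 and 4, 371 without mutant fasted replicate 3, and 33 in a fit of only these 8 arrays. After a second quantile normalization 468 genes were called, 251 higher and 217 lower. The fit of only the arrays compared called more genes with fasting in heterozygotes (568) than in mutants. Gpcpd1 lost its call without any 1 of 11 arrays, Got1 and Gstp3 of 5, Fam13a of 4, Hsd3b3 and Cyp2c70 of 3, Hsd3b2 of 2 and Slc25a25 of 1, with adjusted p up to 0.11.

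By list, 8 of 24 fatty acid and triglyceride synthesis genes fell in fasted mutants and 2 rose (11 and 2 when adjusted over the list alone, camera adjusted p = 2.2e-05, and adjusted p = 0.22 with an estimated correlation). Elovl6 fell by 1.12 ± 0.14 and Acaca by 0.97 ± 0.11. Of 20 cholesterol synthesis genes 7 fell (19 when adjusted over the list alone, camera adjusted p = 1.1e-11, and adjusted p = 0.22 with an estimated correlation). Lss fell by 0.96 ± 0.22 and Pmvk by 0.93 ± 0.18. Of 17 beta-oxidation genes 7 rose (11 when adjusted over the list alone, camera adjusted p = 4.5e-08, and adjusted p = 0.22 with an estimated correlation). Cpt1a rose by 0.46 ± 0.10 (adjusted p = 0.023), and of 29 PPAR-alpha targets 5 rose (15 higher and 2 lower when adjusted over the list alone, camera adjusted p = 3.7e-07, and adjusted p = 0.36 with an estimated correlation). Ehhadh rose by 0.70 ± 0.15. Of 16 gluconeogenic genes 4 rose (5 when adjusted over the list alone, camera adjusted p = 0.00018, and adjusted p = 0.20 with an estimated correlation). G6pc, glucose-6-phosphatase, rose by 0.73 ± 0.17. Cell cycle genes fell, 5 of 23 (10 when adjusted over the list alone, camera adjusted p = 8.4e-09, and adjusted p = 0.20 with an estimated correlation). Rrm2 fell by 0.63 ± 0.15 and Top2a by 0.55 ± 0.13. Of 16 genes of pericentral hepatocytes 4 fell (6 when adjusted over the list alone, camera adjusted p = 0.00016, and adjusted p = 0.27 with an estimated correlation). Rgn fell by 0.94 ± 0.17. Of 15 xenobiotic response genes 4 fell (9 when adjusted over the list alone, camera adjusted p = 7.6e-05, and adjusted p = 0.0503 with an estimated correlation). Cyp2c29 fell by 0.60 ± 0.14. Unfasted mutant replicate 1 held Cpa1 at 12.29. Without it 13 cell cycle genes fell, 10 PPAR-alpha targets and 10 beta-oxidation genes rose, and 9 cholesterol synthesis genes and 6 xenobiotic response genes fell. Lss and Cpt1a each lost their call without any 1 of 2 arrays, Rrm2 of 3, G6pc and Cyp2c29 of 4, Top2a of 5 and Ehhadh of 1, with adjusted p up to 0.091. Camera also called mitochondrial biogenesis (adjusted p = 0.00079), macrophage markers (0.0029), the mitochondrial unfolded protein response (0.0044) and periportal genes (0.019) as higher, and stellate cell (0.00081), cholangiocyte (0.0045) and neutrophil markers (0.039) as lower. With an estimated correlation their adjusted p lay between 0.219 and 0.65. Neutrophil markers lost their call without any 1 of 5 arrays (adjusted p up to 0.14), and macrophage markers, the mitochondrial unfolded protein response and periportal genes each without 1 (0.14, 0.15 and 0.062).

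The interaction asked whether the fasting response differed between genotypes, whose fasts were not matched in length. It was called for 2 genes, Hsd3b5 and Xkr9, both with a more positive change in mutants. Hsd3b5 differed by 3.87 ± 0.49 (adjusted p = 0.015), falling from 10.84 ± 0.81 (SD, n = 4) to 6.93 ± 0.77 in heterozygotes and reading 5.55 ± 0.11 and 5.52 ± 0.07 in unfasted and fasted mutants, where it was dim, below the lower quartile of every array (5.94 to 6.02). A change of -3.91 from that level, as in heterozygotes, would end below 3.795, the lowest value on any array, so for Hsd3b5 the test could not have found an equal change, and a different fasting response was not shown. Xkr9 differed by 0.95 ± 0.14 (adjusted p = 0.04995), falling by 0.83 ± 0.10 in heterozygotes (adjusted p = 0.00078) and reading 0.12 ± 0.10 higher in fasted mutants (adjusted p = 0.48). At an unadjusted p under 0.05 limma gave 2189 genes, and no gene passed an adjusted p of 0.01. Leaving out 1 array gave between 0 and 6 genes, Hsd3b5 lost its call without any 1 of 6 arrays (adjusted p up to 0.057) and Xkr9 without any 1 of 13 (up to 0.19). For Fgf21 the interaction was -1.04 ± 0.32 (adjusted p = 0.36), so its fasting changes of 0.27 in heterozygotes and -0.77 in mutants were not shown to differ.

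The fasting changes of the 2 genotypes correlated across 19938 genes with r = 0.433, over genes that are not independent replicates. Leaving out 1 array gave r between 0.382 and 0.460. These comparisons share no array, and simulated groups with no effect gave 0.001. That value lies near 0 by construction, since the simulated genes varied independently, so it is no benchmark. Of the 313 genes called in heterozygotes 87.9% changed in the same direction in mutants, and 78 were called in both, 49 higher and 28 lower in both, where independent lists would share 3.4 and 1.7. The slope of the mutant on the heterozygous change over the called genes was 0.484, and 0.528 when genes were chosen on some heterozygous arrays and measured on the others. Both slopes are biased low, the first by choosing genes on the same arrays and the second by noise in the few held-out arrays. Neither thus gives the size of the mutant response. The genotype effect in the unfasted state was then set against the heterozygous fasting effect, which share the unfasted heterozygous arrays. Here r was 0.322 with a covariance of 0.0139. Simulated groups with no effect, which shared controls in the same way, gave r = 0.501, above the observed r. Their covariance was 0.00504, a difference of 0.00881. The simulation used 1 spread per gene pooled over all groups. The median SD of a gene was 0.07 in the shared unfasted heterozygotes and 0.11 in unfasted mutants, so the simulated covariance can be too high. With the shared arrays split 2 and 2, r was 0.191 and the covariance 0.00895. The 2 comparisons shared 112 called genes, 101 with the same sign (35 higher and 66 lower), where independent lists would share 6.2 and 6.2, a figure that leaves out the shared arrays, and simulated groups with no effect shared 0, which is no benchmark because they called at most 2 genes in either comparison. With each comparison called against its own pair of these arrays, a test chosen after seeing the data, they shared a mean of 21 genes over 6 splits (between 8 and 33), 4.5 higher and 12.3 lower in both, where independent lists would share 0.558 and 0.738. Of the genes so called with fasting a mean of 67.2% had the same sign (between 50.7% and 75.4%).

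**Figure D3:**
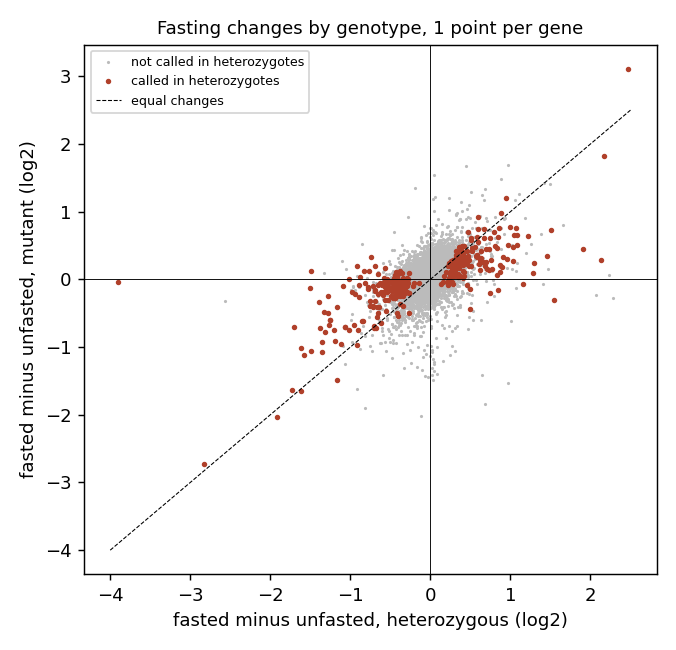
Log2 change with fasting in mutants (vertical axis) against that in heterozygotes (horizontal axis), 1 point per gene, with genes called in heterozygotes in red and a dashed line where both changes are equal. Most red points lie at the lower left and upper right, and 87.9% of them have the same sign, and Hsd3b5 lies at the left with a change of -3.91 in heterozygotes and -0.03 in mutants.

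Over all contrasts 87 list tests were called with camera. Only 2 held with an estimated correlation, the female-biased list in unfasted mutants and the fatty acid and triglyceride list in fasted heterozygotes. The median, mean and camera test differed in sign only for lists that were not called, among them the acute phase list between unfasted groups, the interferon and periportal lists between fasted groups, and the endothelial list in both fasting contrasts. The periportal list had a median of 0.01 and a mean of -0.07 between fasted groups. In 86 of the 87 the adjusted p with an estimated correlation was the highest over the alternatives run. Of the genes named with a call, 49 of 80 in the unfasted genotype contrast, 61 of 80 in the fasted one, 19 of 42 in heterozygous fasting and 22 of 50 in mutant fasting kept it without each array in turn.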

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

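The tests of pancreatic tissue, of hepatocyte share, of gene families, of growth hormone signalling and of exchanged residuals were chosen only after the results they bear on were seen, while the sex test and the counts over other splits of the arrays were fixed earlier.

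Male-biased genes were lower and female-biased genes higher in mutants in both feeding states. Female mice among the mutants are argued against by Xist and 3 Y-linked genes, whose median differed between genotypes by at most 0.148, with Xist between 5.21 and 5.46 on all 16 arrays. Probes shared within gene families, as the whole cause, are argued against by 11 members without close paralogs, for these members only. Their median shift in the direction of their list was 0.63 unfasted and 0.605 fasted, and between 0.32 and 0.82 on single mutant arrays. The 11 were picked after the values were seen and include the growth hormone axis genes Igf1, Igfals and Ghr. Of these Igf1 changed by 0.01 fasted. How much shared probes add to the shifts within families was not tested. Lower growth hormone signalling through STAT5 stays open in both feeding states, since its targets Igf1, Igfals, Socs2 and Cish went both ways, with changes of -0.21, -0.79, 0.83 and -0.49 unfasted (median -0.352, limma adjusted p = 0.04, 0.026, 0.301 and 0.4) and of 0.01, -0.605, 2.20 and 0.72 fasted (median 0.366, limma adjusted p = 0.941, 0.06, 0.0051 and 0.134). A change in liver sex bias with the genotype by another route was not tested.

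The ATF4 list and Fgf21 were higher in unfasted mutants, and unfasted mutant replicate 1 held acinar transcripts, such as Ctrb1 at 12.64 against at most 7.63 elsewhere. Pancreatic tissue as the whole cause is argued against by the other 3 unfasted mutant arrays, whose list medians lay between 0.302 and 0.83, above the heterozygous range of -0.06 to 0.06. Fgf21 without that array was still 1.43 ± 0.21 higher (limma, adjusted p = 0.0017). The array itself had the highest list median, 1.13, so pancreatic tissue may add to the size of the shift. A stress response to the genotype is a candidate explanation that the data leave open.

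Macrophage and endothelial markers were higher in fasted mutants, where camera also called lymphocyte and stellate cell markers. Endothelial markers were higher in unfasted mutants, where it also called macrophage, stellate cell, neutrophil and cholangiocyte markers. None of these list calls held with an estimated correlation (camera adjusted p between 0.084 and 0.52). As the whole cause, a lower share of hepatocytes should raise the markers of other cell types together. A change of a dim probe set can be understated and the lists were not matched for brightness, so unequal shifts cannot exclude this cause. Between fasted groups the macrophage shift exceeded those of lymphocyte, stellate cell, neutrophil and cholangiocyte markers by 0.496, 0.54, 0.64 and 0.71. Each had an exact two-sided permutation p of 0.0286, the smallest possible with 4 against 4. The endothelial shift between fasted groups exceeded those of lymphocyte, stellate cell, neutrophil and cholangiocyte markers by 0.194, 0.24, 0.34 and 0.40, with the same exact p. Between unfasted groups the endothelial shift exceeded those of cholangiocyte and lymphocyte markers by 0.206 and 0.288 (exact permutation p = 0.0286 each). It exceeded that of stellate cell markers by 0.096 (exact permutation p = 0.286) and that of neutrophil markers by 0.23 (exact permutation p = 0.0571). In neither feeding state can a lower hepatocyte share and a change in macrophages or endothelial cells be told apart. Whether cell numbers or expression per cell changed was not tested.

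The real groups were compared with other splits of the same arrays. For the unfasted genotype contrast 1 of 35 splits, the real one, gave as many as 1584 genes, and the highest other gave 229. For the fasted genotype contrast it was 1 of 35 with 2716 genes, and no other split called a gene. For fasting in heterozygotes it was 1 of 35 with 313, and the highest other gave 5. For fasting in mutants it was 1 of 35 with 667, and the highest other gave 348. In each of these 4 contrasts the real split thus gave the most genes. A share of 1 of 35 is the smallest these splits can give, and the 4 tests were not adjusted, so chance was not excluded. The mutant fasting count was also lower, at 33 genes, in a fit of only the arrays compared. For the interaction 5 of 100 drawn splits gave as many as the 2 genes called, the highest other with 189, so this count did not exclude chance. In that split all 4 fasted mutant arrays stood with 1 fasted and 3 unfasted heterozygous arrays, so the fasting response common to both genotypes enters such counts. With residuals of a model without the interaction exchanged over the same 100 splits, 3 gave as many as 2 genes, the highest other with 2. The exact 95% limits of that share, 0.623% to 8.52%, include 5%, so whether chance grouped the arrays stays open for the interaction.

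Some arrays stood apart from the other 3 of their group, by the gap to the nearest array relative to the range of the group. This held in 28 of 416 groups tested (6.73%), where chance gives 5% for normally spread values. The ratio also flags small gaps where the other 3 arrays agree. An example is the median of all probe sets on unfasted heterozygous replicate 1, 7.363 against 7.3748 to 7.3754. Among genes, unfasted mutant replicate 1 read 12.78 for Cyp2b9, 9.957 for Slc25a25 and 9.386 for Tmem120a. Unfasted mutant replicate 2 read 11.339 for Keg1, and replicate 4 read 11.67 for Pigr and 11.805 for Cpt1a. Fasted mutant replicate 1 read 9.545 for Acnat2 and 7.537 for Dpy19l3, and replicate 4 read 9.304 for Srebf1. Unfasted heterozygous replicate 1 read 11.134 for Elovl3 and replicate 2 read 9.665 for Mmut. Fasted heterozygous replicate 3 read 7.724 for Cyp2a22 and 12.693 for Got1.

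Among list medians, relative to the unfasted heterozygous mean, the pancreas and adipose list stood at 2.494 on unfasted mutant replicate 1, the lymphocyte list at 0.319 on replicate 3 and p53 targets at 0.12 on replicate 4. Fasted mutant replicate 2 stood apart for the mitochondrial unfolded protein response (0.484), pericentral genes (-0.51) and erythroid markers (-0.117). In unfasted heterozygotes replicate 4 stood apart for mitochondrial biogenesis (-0.046) and female-biased genes (-0.186), and replicate 1 for the xenobiotic list (0.257) and for the median of all probe sets (7.363). In fasted heterozygotes replicate 3 stood apart for the tricarboxylic acid cycle (0.082) and gluconeogenesis (0.544), replicate 4 for glycolysis (-0.09), and replicate 1 for the circadian list (-0.123) and neutrophil markers (0.169).

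The interaction test called Hsd3b5 (3.873) and Xkr9 (0.95). Hsd3b5 was dim in mutants, at 5.55 unfasted and 5.52 fasted, too low to fall as in heterozygotes, and lost its call without any 1 of 6 arrays, and Xkr9 without any 1 of 13. Camera called 14 lists, none of which held with an estimated correlation, where adjusted p lay between 0.197 and 0.583. Their medians, as mutant minus heterozygous fasting change, were positive for macrophage markers (0.367), male-biased genes (0.238), the interferon response (0.218), endoplasmic reticulum stress (0.192), fatty acid and triglyceride synthesis (0.182), mitochondrial biogenesis (0.172) and glycolysis (0.08). They were negative for pericentral genes (-0.374), the acute phase response (-0.291), the xenobiotic response (-0.199), hepatokines (-0.151), the cell cycle (-0.14), neutrophil markers (-0.121) and stellate cell markers (-0.115). Without 1 array 6 of these calls were lost, that of glycolysis without any 1 of 4 arrays (camera adjusted p up to 0.078), the cell cycle of 3 (0.101), mitochondrial biogenesis of 2 (0.0595), hepatokines of 2 (0.191), male-biased genes of 1 (0.098) and neutrophil markers of 1 (0.067).

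The 13767 probe sets without exactly 1 gene symbol were not part of the comparisons. Tested in the same way, 249 were called between unfasted genotypes (39 higher and 210 lower in mutants) and 512 between fasted ones (372 higher and 140 lower). With fasting 65 were called in heterozygotes and 69 in mutants.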

How the results depend on the processing

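Leaving out unfasted mutant replicate 1 for counts within lists and calling genes against separate pairs of controls were chosen after seeing the data, and the other alternatives given here were planned. No result called changed its direction under any alternative run. Of the calls of named genes the fit of only the arrays compared kept 182 and lost 70, robust moderation lost 18, array weights 15, a second quantile normalization 12, median-centred arrays 11, moderation without a trend 6, and the mean of probe sets and the brighter genes 1 each. Of 87 list calls an estimated correlation kept 2, fry kept 49, and the brighter genes lost 15.

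An adjusted p under 0.01 left 461 and 993 genes for genotype in unfasted and fasted mice, 73 and 79 for fasting in heterozygotes and mutants, and 0 for the interaction, since the threshold is stricter. A 2-fold minimum left 148, 184, 49, 26 and 1. With only the arrays compared the counts were 764 for unfasted genotype, 568 for heterozygous fasting and 33 for mutant fasting. There fewer arrays estimate the spread and each pair of groups has its own. The median SD of a gene was 0.11 and 0.09 in unfasted and fasted mutants and 0.07 in both heterozygous groups, which the main fit pools. The order of the 2 fasting counts thus reversed, so these counts do not show which genotype changed more genes with fasting. Array weights gave 1029 for heterozygous fasting and 1 for the interaction. The interaction gave 1 gene with centred arrays and 0 with robust moderation, and the cause was not tested. Among brighter genes it gave 0, since Hsd3b5, at a mean of 7.21, lies under their limit of 7.67, and Xkr9 lost its call there.

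Without 1 array the counts ranged from 698 to 1781, from 1575 to 3180, from 155 to 358, from 224 to 1941 and from 0 to 6, in the same order of contrasts. The lowest came without unfasted heterozygous replicate 3, fasted mutant replicate 2, unfasted heterozygous replicate 4 and fasted mutant replicate 2, and the 1941 without unfasted mutant replicate 1. Across the genes called in heterozygous fasting the correlation was 0.613 for unfasted genotype against heterozygous fasting, which share controls, 0.567 with these split but genes chosen on all of them, and 0.478 with genes called against a separate pair (between 0.116 and 0.68 over 6 splits). It was 0.768 between the fasting effects, whose Spearman's rho over all genes was 0.278.

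The replicate numbers did not pair the samples, since same-numbered arrays correlated with each other between -0.12 and 0.252 after removal of group means, and not every array correlated best with its own number. With the replicate block the counts were 1672, 2739, 383, 644 and 2, and 10 calls of named genes were not made. Arrays have no detection calls here, so signal over background was not used to limit any result.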

Other observations

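The tests of this part were fixed before their results were seen, except the mirror comparison of fasting responses and the averaging used for it, which were chosen afterwards. The exact limits of the share of genes near Mmut were not part of the condition set earlier.

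Antioxidant, interferon and secreted-signal genes also differed between genotypes. Of 20 NRF2 antioxidant genes 3 rose in unfasted mutants and none fell (6 when adjusted over the list alone, camera adjusted p = 0.0032, and adjusted p = 0.26 with an estimated correlation). In fasted mutants 6 rose and 1 fell (7 and 1 when adjusted over the list alone, camera adjusted p = 0.0019, and adjusted p = 0.32 with an estimated correlation), with Hmox1, heme oxygenase, at 1.60 ± 0.38 and Nqo1 at 1.25 ± 0.28. Of 22 interferon response genes 4 fell and 1 rose in unfasted mutants (5 and 1 when adjusted over the list alone, camera adjusted p = 0.00022, and adjusted p = 0.26 with an estimated correlation). In fasted mutants 2 fell and 1 rose, and the list was not called (3 and 2 when adjusted over the list alone, camera adjusted p = 0.98). In unfasted mutants Dhx58 fell by 0.64 ± 0.09, while Usp18, which restrains interferon signalling, rose by 1.46 ± 0.22 in unfasted and by 1.80 ± 0.22 in fasted mutants. Among 19 hepatokines and secreted signals 4 rose and 1 fell in unfasted mutants (9 and 2 when adjusted over the list alone, camera adjusted p = 0.00050, and adjusted p = 0.084 with an estimated correlation), with Igfbp2 at 1.41 ± 0.19. In fasted mutants 2 rose and 1 fell, and the list was not called (2 and 1 when adjusted over the list alone, camera adjusted p = 0.31).

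One-carbon and sulphur amino acid genes moved both ways. In fasted mutants 5 of 18 fell and 1 rose (9 and 1 when adjusted over the list alone, camera adjusted p = 0.022, and adjusted p = 0.45 with an estimated correlation), a camera call that was lost without fasted mutant replicate 1 or fasted heterozygous replicate 3, with adjusted p up to 0.070. Gldc, of the glycine cleavage system, fell by 1.13 ± 0.25 and Dmgdh by 0.57 ± 0.12, while Mthfd1l, a mitochondrial folate enzyme, rose by 0.77 ± 0.14. With fasting, 2 of 22 autophagy and lysosome genes rose in mutants (3 when adjusted over the list alone, camera adjusted p = 0.0014, and adjusted p = 0.20 with an estimated correlation), with Atg2a at 0.48 ± 0.09. In heterozygotes 1 rose (2 when adjusted over the list alone, camera adjusted p = 0.0074, and adjusted p = 0.16 with an estimated correlation), and the interaction was not called for this list (camera adjusted p = 0.51).

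Donor-strain DNA around the targeted locus could leave a cluster of changed genes beside Mmut. Of the 100 measured genes nearest Mmut 4% were called with the same sign in both feeding states, against a median of 4% over 17028 windows on other chromosomes, whose central 95% reached up to 9%. Many of the 100 were olfactory receptor genes, none called in both states, and the windows were not matched for such genes. A cluster among the remaining genes could thus be diluted. A share at or below the median of the windows was the condition set earlier for no such cluster, and 4% met it. The exact 95% limits of that share, which that condition did not include, were 1.10% to 9.93% and pass 9%. An excess was thus neither shown nor excluded. The 4 genes, named after their values were seen, were Cyp39a1 (1.95 unfasted and 1.31 fasted), Pla2g7 (1.22 and 1.10), Tnfrsf21 (0.78 and 0.77) and Slc25a27 (0.46 and 0.50), and they lay between the 14th and the 24th nearest.

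A shorter fast in the mutants could give a smaller fasting response. Over 313 genes chosen on some heterozygous arrays, the mean change was 0.481 on the other heterozygous arrays and 0.311 in mutants, a ratio of 0.647, between 0.537 and 0.728 without any 1 array. This met the condition set earlier for a shorter fast. Genes chosen instead on mutant arrays gave a mutant to heterozygous ratio of 1.17, between 0.996 and 1.30 without any 1 array, so a smaller response of mutants was not shown on those genes. Averaging the ratios themselves, as first computed, gave 0.650 for the first choice of genes. For the second it gave a heterozygous to mutant ratio of 0.911, which passed 1 without unfasted mutant replicate 2 (2.22) and fasted mutant replicates 2 (1.07) and 3 (1.002), and was 0.789 at the lowest without any 1 array. The length of the fast differs with genotype by design, so a shorter fast and a weaker response to fasting in mutants cannot be told apart.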
